A study of Mus musculus with 12 samples.

How the data were processed

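Total RNA of 12 samples from C57BL/6 mice with Lewis lung carcinoma was sequenced, with 3 replicates in each of 4 groups, namely resident macrophages, marrow-derived macrophages, total colony cells and Kit-negative colony cells. RNA was extracted with an RNeasy kit and stranded total RNA libraries were prepared with a TruSeq kit, per the labels' protocols. Reads were processed with FastQC, STAR 2.5.3a, RSEM 1.3.0 and MultiQC on the mm10 build, GRCm38, per the submitters' processing notes. The gene values were deposited as RSEM expected counts, which are estimated read numbers per gene without scaling, per the file headers. The same table was deposited with TPM values, which RSEM scaled by effective transcript length and to a fixed sum per library, per the file headers. The annotation release and any read filter are not given in the sources used here. Nothing in the labels says whether the replicates of a group are separate animals or cultures, so each p-value measures only the spread between these samples.

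The table held 36793 Ensembl genes. Gene names came from a list of current symbols by Ensembl identifier, which matched 35243 of the identifiers, and the 1550 unmatched ones held 0.406% of the counts. Coordinates came from the GENCODE vM21 annotation on GRCm38. The table lists no gene that this annotation places on the mitochondrial genome or the Y chromosome. Of the expected counts above 0, 74.3% were whole numbers within 0.005, and all were rounded to whole counts. Library totals ran from 22.4 to 28.9 M counts, at which 3 counts in a library corresponded to 0.0939 to 0.148 CPM. These floors and the lower bounds on folds cover counting error only.

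Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed edgeR's expression filter by group, which left 14274 genes, and libraries were scaled with TMM factors. A single quasi-likelihood model with robust moderation was fitted to all 12 samples, with 1 coefficient per group and 8 residual degrees of freedom. The biological coefficient of variation was 0.186. The comparisons were resident against marrow-derived macrophages, total colony cells against resident macrophages, and Kit-negative against total colony cells. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. All CPM are TMM-scaled and given as mean ± SD of 3 libraries.

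A set of 27 gene lists with 441 genes covered sort markers, blood lineages, tumor epithelium and stroma, growth, macrophage activation, metabolism, cytokine receptors and the immediate early response. The lists were tested with camera from limma 3.58.1 on log2 CPM with a preset correlation of 0.01, with adjustment over the 27 lists, and again with a correlation estimated per list. Each list also has a count of its single genes with p adjusted over the list alone. Ly6g and other members below the filter were not tested. The groups, comparisons, gene lists, test, threshold, the first set of alternatives and the rule for named genes were chosen before the data were examined.

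The text draws its named genes from the sort markers and cytokine receptors and from the 8 largest rises and 8 largest falls per comparison among called genes with at least 20 CPM in the higher group and no overlap between replicates, without predicted genes, pseudogenes and ribosomal RNA. From each list it draws on up to 3 genes with the largest change in the majority direction and up to 1 in the other, with at least 1 CPM in either group. Genes named outside this rule are described as chosen after their values were seen. Where a group had 0 counts, folds are lower bounds against 3 counts over the group.

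The procedure was tested on simulated counts with 200 changed genes per comparison, 100 at each of 2 fold sizes. For resident against marrow-derived macrophages, with 13996 genes, it called 65% of genes changed 2-fold and 90% of those changed 4-fold, with 9 unchanged genes called. For total colony cells against resident macrophages, with 13995 genes, it called 71% and 97%, with 14 unchanged genes called. For Kit-negative against total colony cells, with 14083 genes, it called 68% and 96%, with 7 unchanged genes called. In each case the seeded gene list was called and 0 other lists. The simulated genes were drawn independently of each other, so this does not test lists whose genes vary together. Each simulated gene also had the same spread in every group. Calls between groups with a larger spread than the others, as found below for colony cells, are thus not tested either.

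Replicates carry the same numbers in each group. Over 10660 genes with a mean of at least 5 CPM, the deviations of same-numbered resident and marrow-derived libraries from their group means correlated at 0.24, 0.29 and 0.19, so the numbers were taken to pair these libraries. The main fit was set before this was seen, and its p-values leave the pairing out. The alternatives tried were DESeq2 size factors, library size alone, no low-count filter, a filter of 1 CPM in 3 samples, the replicate number as a block, a fit of only the 6 libraries compared, each replicate left out in turn, the Wald test of DESeq2 1.42.0, and limma-trend on log2(TPM + 1). Alternatives added after the data were seen were the block in a fit of the 6 tumor libraries and the omission of genes highest in colony cells, of genes over 10 times higher in tumor macrophages, and of X-linked genes. In each comparison, the 10 splits of the 6 libraries into groups of 3 were also tested.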

Results

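RNA sequencing compared 4 cell populations tied to Lewis lung carcinoma, a mouse lung tumor line that was grown in C57BL/6 mice, with 3 libraries per population. Resident macrophages were sorted from dissociated tumors as CD45+ CD11b+ cells that were negative for Gr1 and high for F4/80. Marrow-derived macrophages were sorted as CD45+ CD11b+ cells that were positive for Gr1 and low for F4/80, per the sorting protocol, while the library names call them low for Gr1. CD45 is encoded by Ptprc, CD11b by Itgam and F4/80 by Adgre1, while the Gr1 antibody binds Ly6G and Ly6C proteins. The other populations came from colonies grown from the Gr1-negative, F4/80-high cells in methylcellulose, a semisolid medium, with the cytokines SCF, IL3 and IL6. Total colony cells were sequenced as grown and Kit-negative colony cells after a sort for absence of Kit, the SCF receptor. The labels call both colony populations macrophage progenitors.

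The resident libraries held 26.8 to 27.2 M counts and the marrow-derived libraries 22.4 to 23.6 M counts. The total colony libraries held 25.9 to 26.4 M counts and the Kit-negative libraries 25.5 to 28.9 M counts. The first principal component carried 83.4% of the variance and set the 6 colony libraries apart from the 6 tumor libraries. The second carried 9.1% and set resident apart from marrow-derived macrophages.

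**Figure D1:**
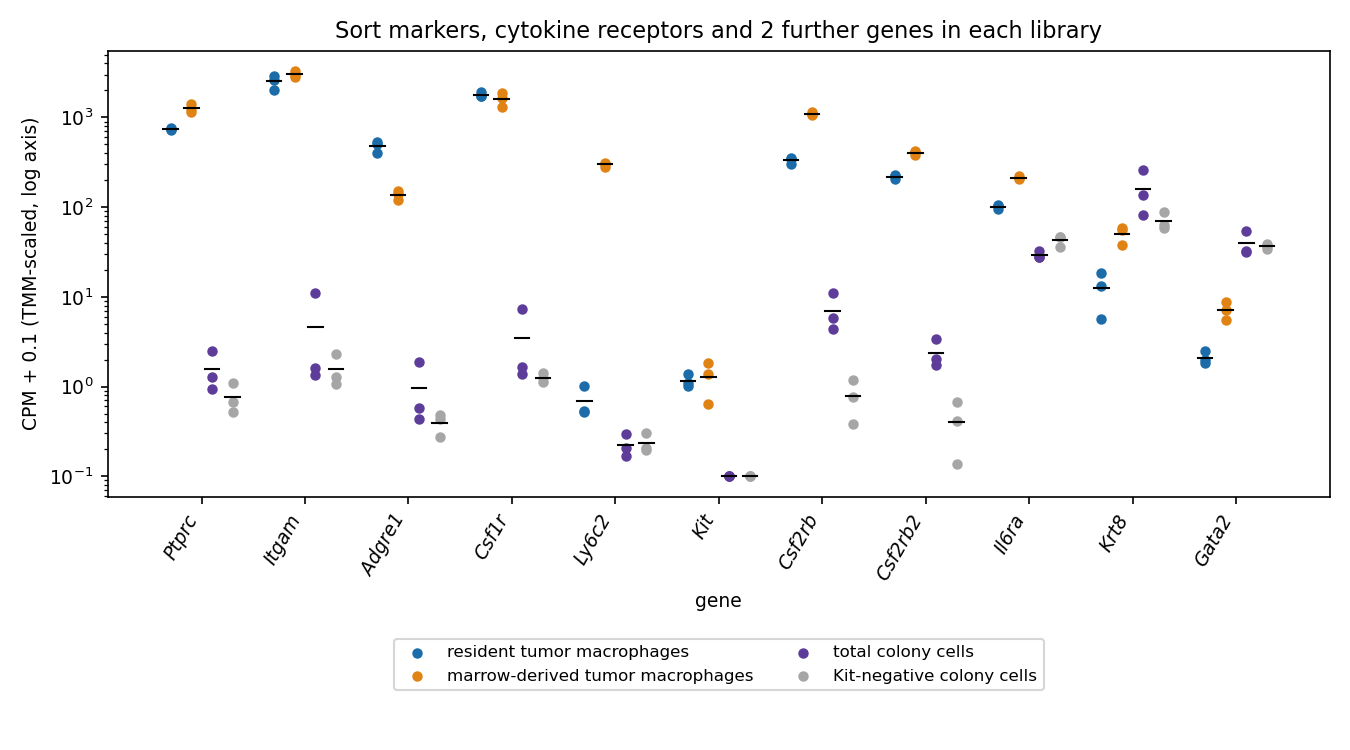
Each point is 1 library and each black bar a group mean, in TMM-scaled CPM plus 0.1 on a log axis, for sort markers, cytokine receptors, Krt8 and Gata2 in the 4 groups of 3 libraries. Ptprc stood at 746 CPM on average in resident macrophages and at 1.48 CPM in total colony cells, and Kit had no counts in any of the 6 colony libraries.

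The first comparison asked how resident and marrow-derived macrophages of the tumor differ. Resident cells carried more transcripts of tissue macrophage and cell cycle genes, and fewer of monocyte, neutrophil, inflammatory, interferon-stimulated and immediate early genes. Of these 7 lists, the monocyte list passed with an estimated correlation, at an adjusted p of 0.0302, and the other 6 did not, at 0.128 each. Folr2, a folate receptor of tissue macrophages, stood at 194 ± 29.0 CPM (SD, n = 3) in resident cells and at 2.40 ± 0.912 CPM in marrow-derived cells, an 80.3-fold difference. Chil3, a chitinase-like protein of myeloid cells, stood at 3.35 ± 0.953 CPM in resident cells and at 1189 ± 144 CPM in marrow-derived cells, a 355-fold difference. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, was 33.8-fold lower in resident cells, at 535 ± 220 CPM against 18110 ± 1190 CPM.

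In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7157 of 14274 tested genes differed at an adjusted p under 0.05. Resident cells were higher for 3700 of them and lower for 3457, and 3349 of the 7157 differed by more than 2-fold. Which direction held more genes depended on the setting, with 3234 higher and 3800 lower under DESeq2 size factors, 3074 and 3704 with a filter of 1 CPM, and 3401 and 3933 with DESeq2. More genes were lower in each fit without 1 library except that without marrow-derived replicate 1, with 2577 higher and 3308 lower without marrow-derived replicate 3. Cspg4 (ENSMUSG00000032911, chromosome 9, 56865033 to 56899870, GRCm38), which encodes the NG2 proteoglycan, had the largest rise that met the rule for named genes, from 3.09 ± 1.08 CPM in marrow-derived to 279 ± 61.5 CPM in resident cells. Col14a1, Fcna and Gas6 were 78.2-fold, 65.7-fold and 68.7-fold higher in resident cells. Cd177 (ENSMUSG00000052212, chromosome 7, 24743983 to 24760311), a surface glycoprotein of neutrophils that the fixed monocyte list also holds, had the largest fall, from 84.6 ± 8.45 CPM in marrow-derived cells to 4 counts in all over the 3 resident libraries. Hp, the gene of haptoglobin, and Sell, the gene of L-selectin, were 294-fold and 191-fold lower. A set of 50 genes was abundant in colony cells and at least 10 times lower in the mean of the 2 tumor groups. Of these, 45 were lower and 0 higher in resident than in marrow-derived cells. When the 6103 of the 14274 tested genes with their highest level in colony cells were left out, a step chosen after the data were seen, 4254 genes differed. Fewer genes were tested in that fit, so 4254 against 7157 does not measure a loss of calls.

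The sort markers followed the gates in part. Adgre1 was higher in resident cells, at 479.8 ± 71.5 against 137 ± 14.7 CPM, and Ptprc was lower, at 746 ± 21.6 against 1260 ± 136 CPM. Ly6c2 was 508-fold lower in resident cells, at 0.586 ± 0.276 CPM against 300 ± 18 CPM, and Ly6c1 was 2.83-fold lower. Reads can be shared between these paralogs, so the split between them is uncertain. Ly6g was too low to test, with 0 counts in each resident library and 7, 1 and 1 counts in the marrow-derived libraries. Itgam did not pass the test, at 2522 ± 443 against 3047 ± 223 CPM, with an adjusted p of 0.70. A fit of the 6 tumor libraries with the replicate number as a block, added after the data were seen, gave Itgam a log2 difference of -0.30 and an adjusted p of 0.0424, against 0.0731 in those libraries without the block. Kit was at 1.06 ± 0.191 and 1.18 ± 0.598 CPM with an adjusted p of 0.803. The list of 6 tested sort markers, with 1 member higher and 3 lower (1 and 3 adjusted over the list alone), did not stand apart from other genes in limma's camera test, with an adjusted p of 0.222.

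Of 26 tested resident macrophage genes, 21 were higher and 2 lower in resident cells (21 and 2 adjusted over the list alone). Lyve1, a hyaluronan receptor of tissue macrophages, rose 47.7-fold, while Mafb, a macrophage transcription factor, was 2.59-fold lower. Of 30 cell cycle genes, 29 were higher and 0 lower (29 and 0 adjusted over the list alone), with a median log2 difference of 1.64. Birc5, a mitotic survival gene, stood at 59.7 ± 8.73 against 13.6 ± 2.63 CPM, and the mitotic kinase gene Ttk was 4.02-fold higher. Of 24 lysosome and lipid handling genes, 13 were higher and 0 lower (14 and 1 adjusted over the list alone), led by lipoprotein lipase, Lpl, at 156 ± 20.1 against 24.2 ± 1.61 CPM. These 3 lists passed camera with adjusted p of 9.99e-08, 1.87e-13 and 0.0146, and with an estimated correlation the adjusted p was 0.128, 0.128 and 0.251. The Myc and ribosome biogenesis list had 8 of 20 members higher and 0 lower (3 and 0 adjusted over the list alone). Its camera adjusted p of 0.0229 became 0.0573 without resident replicate 3, 0.051 without marrow-derived replicate 3 and 0.666 with an estimated correlation. Polr1b, a subunit of RNA polymerase I, was 1.95-fold higher.

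Monocyte, neutrophil and granule genes lay lower in resident cells. Of 19 monocyte genes, 0 were higher and 16 lower (0 and 16 adjusted over the list alone), and this list kept its camera call with an estimated correlation, at an adjusted p of 0.0302. Of 16 tested mature neutrophil genes, 1 was higher and 14 lower (1 and 15 adjusted over the list alone), with the calprotectin subunit S100a9 at 0.887 ± 1.09 against 66.5 ± 48.8 CPM and the chemokine receptor Cxcr2 75.4-fold lower. Of 6 tested primary granule genes, 1 was higher and 4 lower (1 and 4 adjusted over the list alone). Its camera adjusted p of 0.0129 was 0.18 with the block in the 6 tumor libraries, 0.196 in those 6 libraries without the block and 0.0814 with a filter of 1 CPM. The neutrophil list had a camera adjusted p of 3.16e-07, and with an estimated correlation both neutrophil and granule lists had an adjusted p of 0.128.

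Inflammatory, interferon and immediate early genes were also lower in resident cells. Of 19 tested inflammatory cytokine and chemokine genes, 3 were higher and 12 lower (3 and 12 adjusted over the list alone). Ptgs2, the inducible cyclooxygenase, stood at 22.8 ± 9.58 against 773 ± 90.3 CPM, the neutrophil chemokine Cxcl3 was 23.7-fold lower, and the chemokine Ccl8 was 19.1-fold higher. Of 22 interferon-stimulated genes, 0 were higher and 19 lower (0 and 19 adjusted over the list alone), with the antiviral enzyme gene Oas3 at 12.0 ± 1.71 against 104 ± 15.3 CPM. Of 16 immediate early and dissociation genes, 0 were higher and 14 lower (0 and 14 adjusted over the list alone), with the nuclear receptor gene Nr4a1 15.1-fold and the stress factor gene Atf3 6.70-fold lower. The 14 tested immune checkpoint and suppression genes split into 1 higher and 8 lower (1 and 8 adjusted over the list alone). Arg1, arginase 1, was 3.55-fold higher at 2599 ± 1080 CPM, while the paralog Arg2 was 15.3-fold lower. Camera gave these 4 lists adjusted p of 0.00247, 1.40e-06, 4.13e-06 and 0.0122, and with an estimated correlation 0.128, 0.128, 0.128 and 0.144.

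Markers of other cell types also lay lower in resident cells. Of 13 tested tumor epithelial and stromal genes, 0 were higher and 11 lower (0 and 11 adjusted over the list alone), with keratin 8, Krt8, at 12.3 ± 6.34 against 50.6 ± 11.3 CPM and the collagen gene Col1a1 at 6.00 ± 0.362 against 24.8 ± 0.967 CPM. Of 15 dendritic cell genes, 0 were higher and 8 lower (0 and 8 adjusted over the list alone), with Cd24a 21.0-fold lower. Of 12 tested T and NK cell genes, 1 was higher and 9 lower (1 and 9 adjusted over the list alone), with Cd4 6.08-fold higher and Nkg7 5.07-fold lower. Of 20 tested hematopoietic stem and progenitor genes, 3 were higher and 11 lower (4 and 11 adjusted over the list alone), with the receptor Flt3 20.4-fold and the transcription factor Lyl1 4.60-fold lower. Camera gave these 4 lists adjusted p of 0.00201, 0.00318, 0.0146 and 0.0146, and 0.128 for each with an estimated correlation. The T and NK cell call was lost with a filter of 1 CPM, at an adjusted p of 0.325, and the hematopoietic call without the genes highest in colony cells, at 0.445.

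Of the 9 receptors of the added cytokines and colony-stimulating factors, 0 were higher and 6 lower in resident cells (0 and 6 adjusted over the list alone), with a camera adjusted p of 0.0198, or 0.216 with an estimated correlation. Csf2rb, the beta chain shared by several cytokine receptors, stood at 334 ± 28.7 against 1104 ± 40.6 CPM, and Il6ra, the IL6 receptor, at 101 ± 4.83 against 212 ± 7.92 CPM. Csf3r, the receptor of granulocyte colony-stimulating factor, was 14.6-fold lower and Il6st, the signaling partner of Il6ra, 2.23-fold lower. Reads of Csf2rb and its paralog Csf2rb2, which was 1.87-fold lower, can be shared, so their split is uncertain. Csf1r, the receptor of macrophage colony-stimulating factor, did not pass the test, at 1798 ± 105 against 1599 ± 281 CPM. Csf2ra did not pass either, with a log2 difference of -0.40 and an adjusted p of 0.327, but gave -0.42 and 0.00154 with the block in the 6 tumor libraries, and 0.00902 in those libraries without the block.

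The other 10 lists did not pass camera in this comparison, with adjusted p from 0.126 to 0.913. The 14 MHC class II and costimulation genes had 7 members higher and 3 lower in resident cells (8 and 3 adjusted over the list alone), with H2-Eb1 at 867 ± 275 against 195 ± 17.7 CPM. The 18 tested alternative activation genes had 6 higher and 9 lower (6 and 9 adjusted over the list alone), with Retnla 33.3-fold higher and the cytokine gene Il10 5.28-fold lower. Retnla was low and uneven, at 6.11 ± 6.29 against 0.18 ± 0.104 CPM. Of its 456 resident counts, 336 came from 1 library, and the marrow-derived libraries held 11 in all. The 21 angiogenesis and matrix remodelling genes had 9 higher and 6 lower (9 and 7 adjusted over the list alone), with the growth factor genes Igf1 and Pdgfb 52.2-fold and 13.5-fold higher. The 21 hypoxia and glycolysis genes had 1 higher and 4 lower (1 and 4 adjusted over the list alone), with Vegfa 3.33-fold lower. The 11 tested mast cell genes had 3 higher and 5 lower (3 and 5 adjusted over the list alone), with the histamine-forming enzyme gene Hdc 126-fold lower. Of 8 tested megakaryocyte and erythroid genes, 1 was higher and 0 lower (0 and 0 adjusted over the list alone), and of 3 tested eosinophil genes, 1 was higher and 1 lower (1 and 1 adjusted over the list alone). Of 4 tested B cell genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), and this list passed only without resident replicate 2, at an adjusted p of 0.0407 against 0.221. Neither of the 2 tested basophil genes passed, with 0 also adjusted over the list alone. The 18 cholesterol synthesis genes had 1 higher and 4 lower (1 and 3 adjusted over the list alone). Their camera adjusted p was 0.126, against 0.00189 with the block in the 6 tumor libraries and 0.00302 in those libraries without it.

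**Figure D2:**
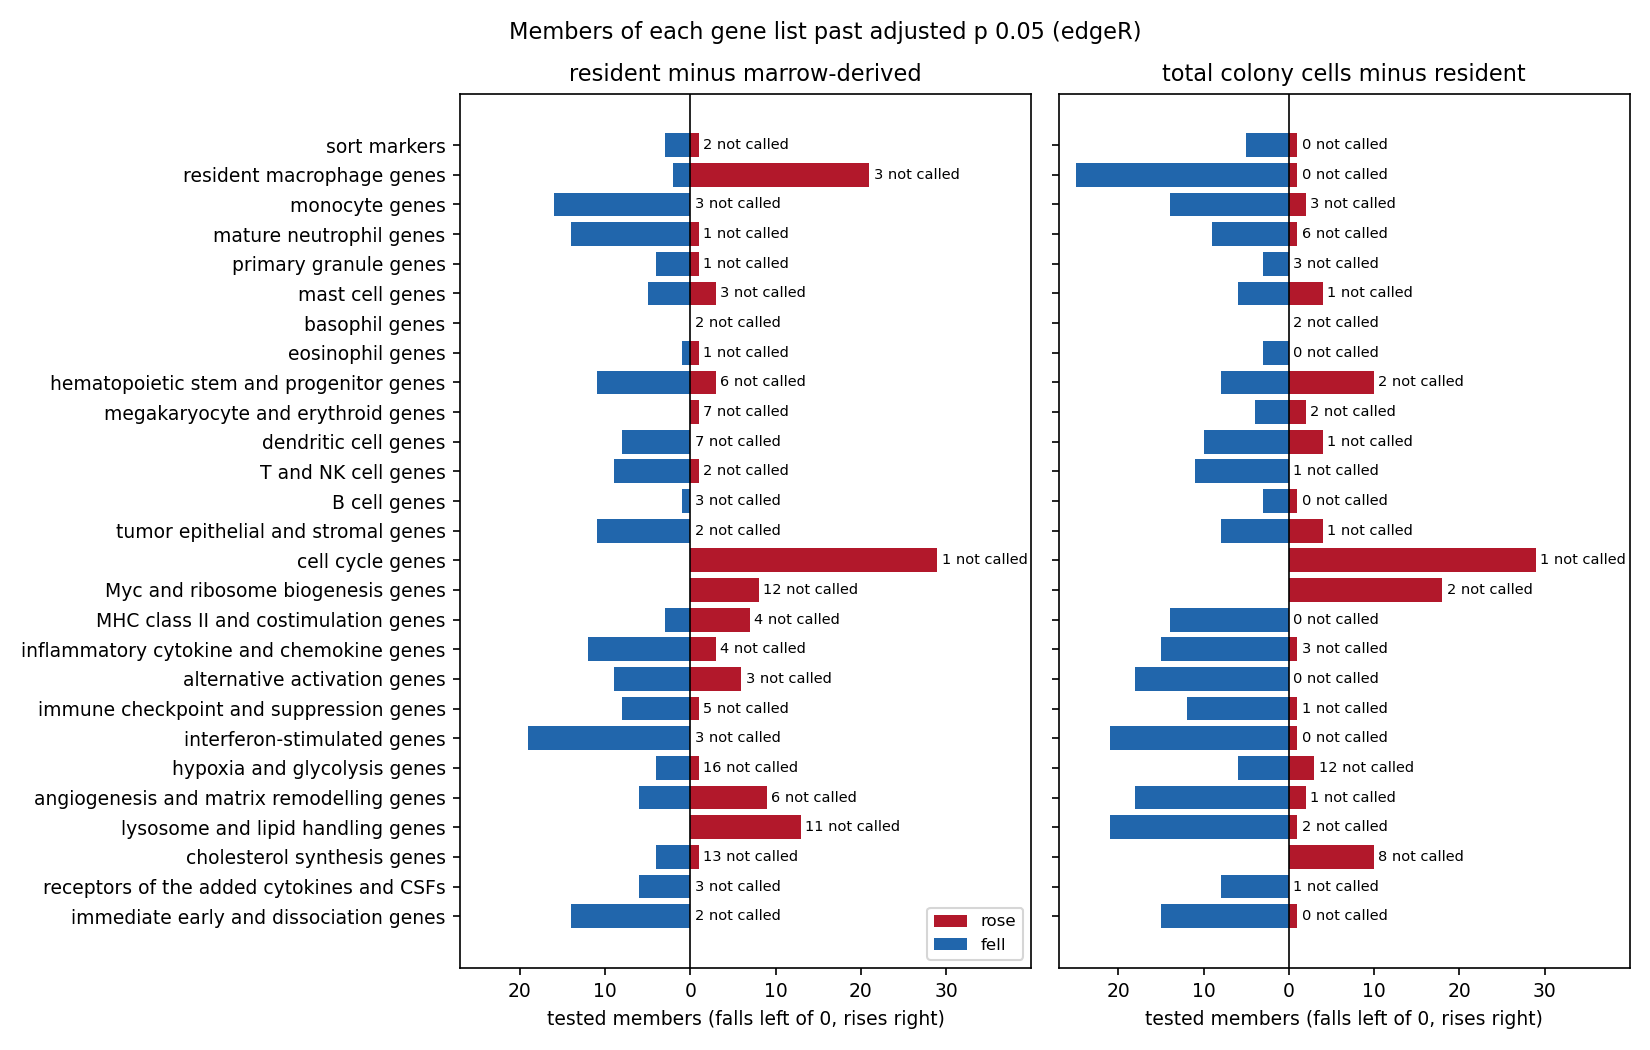
Bars count the tested members of each of the 27 gene lists that rose (right of 0) or fell (left of 0) past an adjusted p of 0.05 in edgeR's quasi-likelihood test, in resident minus marrow-derived macrophages (left panel) and in total colony cells minus resident macrophages (right panel). Cell cycle genes rose in 29 of 30 cases in both panels, and interferon-stimulated genes fell in 19 and 21 of 22 cases.

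The second comparison set total colony cells against the resident macrophages, the population they were grown from. Colony cells held almost none of the macrophage transcripts of the resident cells, and held more transcripts of cell cycle, Myc and ribosome biogenesis genes, although these lists did not pass with an estimated correlation, with adjusted p of 0.212 and 0.40. The 3 chains of complement C1q, encoded by C1qa, C1qb and C1qc, stood at 2033 ± 405, 2049 ± 419 and 1704 ± 361 CPM (SD, n = 3) in resident cells and at 0.481 ± 0.252, 0.479 ± 0.216 and 0.286 ± 0.111 CPM in colony cells. Lyz2, lysozyme of myeloid cells, fell from 21170 ± 3460 to 40.4 ± 44.6 CPM. Lrp2 (ENSMUSG00000027070, chromosome 2, 69424340 to 69586065, GRCm38), the endocytic receptor megalin, rose from 0.394 ± 0.184 to 67.9 ± 12.6 CPM, a 170-fold difference. Krt8, a keratin of simple epithelia, rose from 12.3 ± 6.34 to 159 ± 91.6 CPM.

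In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10165 of 14274 genes changed, with 4901 higher and 5264 lower in colony cells, and 6327 of them changed by more than 2-fold. The direction of small changes depended on the scaling. With library size alone, 6337 genes were higher and 4188 lower, and the median log2 difference over all genes was 0.29 in place of -0.01, while limma on log2(TPM + 1) gave 5883 higher and 3941 lower. Among the largest rises were Tinagl1, Nqo1 and Podxl, at 77.9-fold, 74.5-fold and 59.3-fold, and Sele, the gene of E-selectin, at 54.1-fold. The largest falls included Cd207, the gene of langerin, and Rnf180, which had 0 counts in the 3 total colony libraries and were at least 841-fold and 652-fold lower, against a floor of 3 counts over the group. Gvin1, a large interferon-inducible GTPase with near-identical copies and therefore uncertain, was at least 2580-fold lower on the same floor. Pdgfb fell from 294 ± 33.8 to 0.0691 ± 0.0617 CPM.

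The proteins used for the tumor sort had few transcripts in colony cells. Ptprc fell 506-fold to 1.48 ± 0.807 CPM, Itgam 559-fold to 4.53 ± 5.44 CPM and Adgre1 565-fold to 0.853 ± 0.783 CPM. Kit had 22, 32 and 24 counts in the resident libraries and 0 in each colony library, so it was at least 31.2-fold lower against 3 counts over the group. Ly6c1 rose 25.7-fold to 73.3 ± 32.4 CPM, while its paralog Ly6c2 fell 4.56-fold, and the split between them is uncertain. Of 6 tested sort markers, 1 rose and 5 fell (1 and 5 adjusted over the list alone). The camera adjusted p of this list, 0.0519, was 0.049, 0.0479 and 0.0482 without resident replicates 1, 2 and 3, 0.0274 without total colony replicate 2, 0.0181 with library size alone and 0.029 without a low-count filter. Of the 9 receptors of the added cytokines and colony-stimulating factors, 0 rose and 8 fell (0 and 8 adjusted over the list alone), with a camera adjusted p of 0.00117, or 0.108 with an estimated correlation. Csf2rb fell 48.3-fold to 6.91 ± 3.44 CPM and its paralog Csf2rb2 95.0-fold to 2.28 ± 0.892 CPM, with an uncertain split between them. Csf2ra fell 329-fold to 0.888 ± 0.939 CPM and Csf1r 534-fold to 3.38 ± 3.39 CPM. Il6ra kept 29.4 ± 2.80 CPM after a 3.44-fold fall. Il6st stood at 70.1 ± 6.62 against 56.9 ± 12.8 CPM and did not pass, with an adjusted p of 0.0823. It passed without resident replicate 1, with a log2 difference of 0.50, with library size alone, with 0.60, and with limma, with 0.59.

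Macrophage, antigen presentation and cytokine genes fell in colony cells. Of 26 tested resident macrophage genes, 1 rose and 25 fell (1 and 25 adjusted over the list alone). The median log2 difference was -8.73, or -8.50 with genes at 0 counts set to the 3-count floor. All 14 MHC class II and costimulation genes fell (14 adjusted over the list alone), with H2-Aa at 1355 ± 399 CPM in resident cells and 0.469 ± 0.201 CPM in colony cells. All 18 tested alternative activation genes fell (18 adjusted over the list alone), with Arg1 down 2960-fold to 0.875 ± 0.222 CPM. The alternative activation list kept its camera call with an estimated correlation, at an adjusted p of 0.014, while the other 2 lists had 0.0669 each. Of 19 tested inflammatory cytokine and chemokine genes, 1 rose and 15 fell (1 and 16 adjusted over the list alone), with Ptgs2 the riser at 153 ± 27.6 against 22.8 ± 9.58 CPM. Of 14 tested immune checkpoint and suppression genes, 1 rose and 12 fell (1 and 12 adjusted over the list alone), with the ectoenzyme gene Entpd1 down 409-fold. Of 22 interferon-stimulated genes, 1 rose and 21 fell (1 and 21 adjusted over the list alone), with Ifit2 the riser at 29.3 ± 3.06 against 15.6 ± 4.53 CPM. The last 3 lists had camera adjusted p of 0.000231, 0.000319 and 6.83e-07, and 0.108 each with an estimated correlation.

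Lysosome, matrix and immediate early genes fell with few exceptions. Of 24 lysosome and lipid handling genes, 1 rose and 21 fell (1 and 21 adjusted over the list alone), with the cholesterol exporter Abca1 down 469-fold and the glycoprotein gene Gpnmb up 4.10-fold to 380.1 ± 56.2 CPM. Of 21 angiogenesis and matrix remodelling genes, 2 rose and 18 fell (3 and 18 adjusted over the list alone), with the matrix gene Sparc up 7.39-fold. Of 16 immediate early and dissociation genes, 1 rose and 15 fell (1 and 15 adjusted over the list alone), with Fos down from 2025 ± 252 to 3.36 ± 1.04 CPM and Ier3 up 2.97-fold. Camera gave these 3 lists adjusted p of 3.62e-05, 0.000943 and 6.84e-05, and 0.108, 0.108 and 0.141 with an estimated correlation.

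Growth genes rose. Of 30 cell cycle genes, 29 rose and 0 fell (29 and 0 adjusted over the list alone), with Rrm2, a ribonucleotide reductase subunit, at 310.5 ± 37.8 against 84.7 ± 13.6 CPM and the mitotic activator Cdc20 up 4.06-fold. Of 20 Myc and ribosome biogenesis genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with the polyamine enzyme gene Odc1 at 699 ± 91.0 against 178 ± 20.9 CPM and Cad up 3.18-fold. Camera gave adjusted p of 1.61e-07 and 8.38e-05, and 0.212 and 0.40 with an estimated correlation. Of 18 cholesterol synthesis genes, 10 rose and 0 fell (7 and 0 adjusted over the list alone), with Acat2 up 8.21-fold. This list had a camera adjusted p of 0.0597, against 0.0118 without total colony replicate 2, 0.025 without a low-count filter and 0.0246 in the fit of the 6 libraries compared. Of 21 hypoxia and glycolysis genes, 3 rose and 6 fell (2 and 6 adjusted over the list alone), with an adjusted p of 0.498.

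Of 19 monocyte genes, 2 rose and 14 fell (2 and 14 adjusted over the list alone), with Ccr2 down 914-fold and Vcan, a matrix proteoglycan, up 3.57-fold. Of 16 tested mature neutrophil genes, 1 rose and 9 fell, of 12 tested T and NK cell genes, 0 rose and 11 fell, and of 3 tested eosinophil genes, 0 rose and 3 fell, with the same counts adjusted over the list alone. Camera gave these 4 lists adjusted p of 0.00184, 0.00605, 0.000282 and 0.0333, and 0.108, 0.223, 0.0669 and 0.21 with an estimated correlation. The eosinophil call was lost without a low-count filter, at an adjusted p of 0.0612, and with a filter of 1 CPM, at 0.0837. Of 20 tested hematopoietic stem and progenitor genes, 10 rose and 8 fell (10 and 8 adjusted over the list alone), with no camera call at an adjusted p of 0.761. Its median log2 difference was 0.34 and its mean -0.97, while the test pointed up. Gata2, a transcription factor of blood progenitors and mast cells, rose from 2.00 ± 0.345 to 39.4 ± 12.9 CPM, Meis1 rose 7.86-fold and Hoxa10 11.0-fold, while the transcription factor Lmo2 fell 280-fold. Of 11 tested mast cell genes, 4 rose and 6 fell (5 and 6 adjusted over the list alone). Of 15 dendritic cell genes, 4 rose and 10 fell, of 6 tested primary granule genes, 0 rose and 3 fell, of 8 tested megakaryocyte and erythroid genes, 2 rose and 4 fell, and of 4 tested B cell genes, 1 rose and 3 fell, with the same counts adjusted over the list alone. Neither of the 2 tested basophil genes passed, with 0 also adjusted over the list alone. Camera made no call for these 6 lists, with adjusted p from 0.085 to 0.791, but other settings called 3 of them. The primary granule list had 0.0325 with library size alone and 0.0246 in the fit of the 6 libraries compared, the dendritic cell list 0.0498 with library size alone, and the B cell list 0.0204 without a low-count filter. Of 13 tested tumor epithelial and stromal genes, 4 rose and 8 fell (4 and 8 adjusted over the list alone), with the matrix gene Lum down 97.2-fold and no camera call at an adjusted p of 0.204. Of the 15 genes of this list, Krt8, Krt18 and Col3a1 stood above 20 CPM in each of the 6 colony libraries. A list of 28 general leukocyte genes, chosen after the data were seen, fell in full in total colony cells, with a median log2 difference of -8.85. Of these 28 genes, 25 stood under 5% of the resident level in both colony groups. Arhgdib, Evi2a and Runx1 kept 28.1%, 9.25% and 71.5% of it in total colony cells, and Runx1 lost its call with library size alone, at an adjusted p of 0.126, and with limma, at 0.193.

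The third comparison set Kit-negative colony cells against total colony cells and asked how the sorted cells differ from the unsorted ones. Inpp5d (ENSMUSG00000026288, chromosome 1, 87620312 to 87720507, GRCm38), the lipid phosphatase SHIP1 of blood cells, rose from 5.65 ± 1.04 CPM in total to 30.5 ± 4.71 CPM in Kit-negative cells (SD, n = 3), a 5.39-fold difference. Tgfbi, a matrix protein gene, rose 3.15-fold to 147 ± 29.3 CPM. Sema6d (chromosome 2, 124089969 to 124667770), a semaphorin, fell from 32.6 ± 6.92 to 7.48 ± 2.14 CPM, and Adcyap1r1, a neuropeptide receptor gene, fell 4.45-fold to 5.86 ± 0.878 CPM. The RNA-binding protein gene Igf2bp3 fell 3.09-fold to 11.0 ± 1.51 CPM. Kit itself had 0 counts in each of the 6 libraries, so at this depth total colony cells showed no Kit transcript for the sort to deplete. Whether the differences follow from a removal of Kit-positive cells was not tested.

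In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 309 of 14274 genes changed, 164 up and 145 down, with 188 changed by more than 2-fold. Total replicates 1 and 3 with Kit-negative replicate 3, set against the other 3 colony libraries, gave 2452 genes in the same test. The count of 309 was 96 without Kit-negative replicate 1, 163 without Kit-negative replicate 2 and 18 in a fit of the 6 colony libraries alone. Between replicates, the chi-square per degree of freedom of counts ran from 41.08 to 99.59 in total and 24.79 to 75.76 in Kit-negative cells. It ran from 25.6 to 36.09 in resident and 6.06 to 19.16 in marrow-derived cells. The spread shared by all 12 libraries may thus be too small for colony cells and the 309 calls too many, although a fit of 6 libraries also has less power. DESeq2 called 836 genes and limma on log2(TPM + 1) 188. More genes fell than rose with library size alone, 157 against 147, with DESeq2, 423 against 413, and without total replicate 1, 165 against 110, total replicate 2, 228 against 158, or Kit-negative replicate 3, 111 against 101. Of the 16 genes with the largest rises and falls that met the rule for named genes, 5 kept their call in the fit of the 6 colony libraries: Inpp5d, Tgfbi, Adcyap1r1, Sema6d and Igf2bp3. The other 11 lost it there, among them the transglutaminase gene Tgm2, the actin bundling gene Fscn1, the collagen gene Col8a1, Pdzd4, Lbh and Inpp4b. Leaving out 1 library ended the call of 5 of the 16. Without Kit-negative replicate 1 the adjusted p was 0.0564 for Serpinb9b, 0.0574 for Dkk2, 0.111 for Fn1 and 0.0905 for Chst15. Without Kit-negative replicate 2 it was 0.0623 for Loxl2, 0.086 for Fn1 and 0.0659 for Chst15, and without Kit-negative replicate 3 it was 0.0616, 0.0539 and 0.10 for these genes. Chst15 also lost its call without total replicate 1, at 0.0571.

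Of the 164 genes that rose, 56 lay on the X chromosome, 34.1% against 3.39% of tested genes, and 11 of the 145 genes that fell lay there too. Without X-linked genes, a step chosen after the data were seen, 187 genes changed, 89 up and 98 down. The drop from 309 is larger than the number of X-linked calls, as the refit also ended calls of genes on other chromosomes. The fixed list of 26 tested resident macrophage genes had 0 rises and 1 fall (0 and 1 adjusted over the list alone), a median log2 difference of -0.03 and a camera adjusted p of 0.47. Over 295 genes, chosen after the data were seen, at 100 CPM or more in tumor macrophages and at most 2% of that level in colony cells, the median gene stood at 0.197%, 0.438% and 0.197% of the resident level in the 3 total colony libraries and at 0.12%, 0.129% and 0.0981% in the 3 Kit-negative libraries. Of these 295 genes, 38 fell and 11 rose. Without the 1798 genes over 10 times higher in tumor macrophages than in colony cells, also a later choice, 165 genes changed, 109 up and 56 down. This drop too is larger than the 72 falls and 32 rises that were left out.

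**Figure D3:**
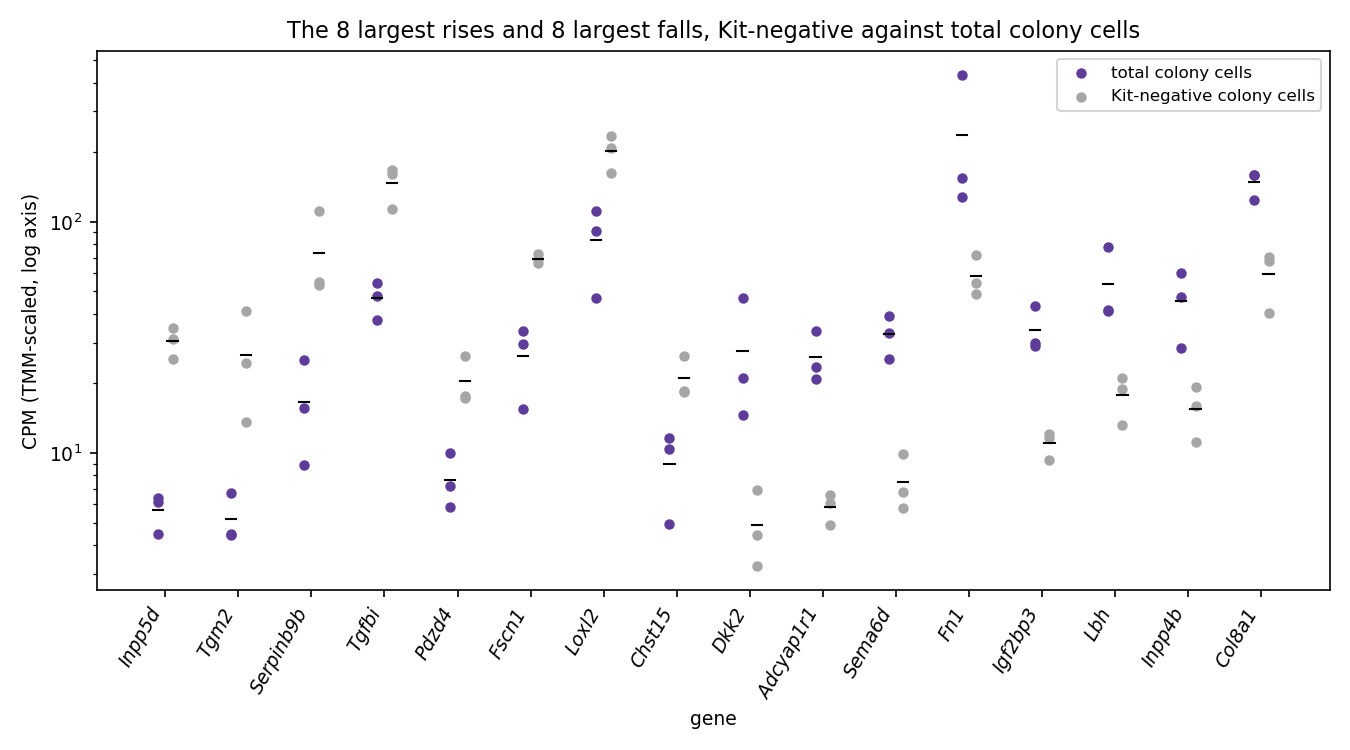
Each point is 1 library and each black bar a group mean, in TMM-scaled CPM on a log axis, for the 8 largest rises and 8 largest falls in Kit-negative (grey) against total (purple) colony cells, with 3 libraries per group. The 16 genes were chosen for groups that do not overlap, which chance gives in 10% of genes with 3 against 3 libraries, and 11 of them kept their call whichever 1 library was left out.

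Among receptor genes, Csf2rb fell 10.3-fold from 6.91 ± 3.44 to 0.674 ± 0.394 CPM and its paralog Csf2rb2 7.25-fold from 2.28 ± 0.892 to 0.305 ± 0.266 CPM, with an uncertain split between them. Itgax, the integrin CD11c, fell 3.77-fold to 2.53 ± 0.335 CPM and the checkpoint receptor gene Havcr2 4.16-fold to 1.26 ± 0.185 CPM. In the fit of the 6 colony libraries these 4 genes had adjusted p of 0.131, 0.242, 0.121 and 0.191. Il6ra rose 1.46-fold to 43.1 ± 6.21 CPM at an adjusted p of 0.0319, which was 0.281 in the 6 colony libraries, 0.0783 and 0.0809 without total replicates 1 and 3, and 0.119 and 0.0964 without Kit-negative replicates 1 and 2. Ptprc, at 0.665 ± 0.300 against 1.48 ± 0.807 CPM, did not pass, with an adjusted p of 0.161. Neither did Itgam, Adgre1 or Csf1r, with adjusted p of 0.298, 0.249 and 0.197. DESeq2 called Ptprc and Adgre1, at 0.0236 and 0.0398. The receptors of the added cytokines had 1 member up and 2 down of 9 (1 and 4 adjusted over the list alone), with a camera adjusted p of 0.546.

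Of the 27 lists, 4 passed camera in this comparison. Cholesterol synthesis genes stood lower at an adjusted p of 0.000383, or 0.882 with an estimated correlation, with a median log2 difference of -0.61 over 18 genes and 0 single members called (0 adjusted over the list alone). The inflammatory cytokine and chemokine list stood lower at 0.0354 and the hematopoietic stem and progenitor list at 0.0437, or 0.871 each with an estimated correlation, with 0 members called in each. Adjusted over the list alone, the first had 0 rises and 5 falls and the second 1 rise and 6 falls. Cell cycle genes stood higher at 0.0492, or 0.882 with an estimated correlation, with a median log2 difference of 0.11 and 0 members called (0 adjusted over the list alone). Without Kit-negative replicate 1 the adjusted p of these lists was 0.15, 0.281, 0.241 and 0.311 in the same order. Without total replicate 1 the hematopoietic and cell cycle lists had 0.0599 and 0.0633, and without total replicate 2 the hematopoietic and inflammatory lists had 0.0987 and 0.143. Without total replicate 3 the hematopoietic, cell cycle and cholesterol lists had 0.134, 0.527 and 0.151, and without Kit-negative replicate 3 the cholesterol list had 0.0632. The hypoxia and glycolysis list passed without total replicate 2, at 0.0228, the basophil list without a low-count filter, at 0.0222, the immediate early list without Kit-negative replicate 2, at 0.00169, and the Myc list without Kit-negative replicate 3, at 0.034. With library size alone 1 list passed, and the cell cycle, hematopoietic and inflammatory lists had 0.0732, 0.0614 and 0.0517, and with a filter of 1 CPM 2 lists passed. The median, mean and test differed in sign for 2 lists that did not pass. Megakaryocyte and erythroid genes had a median log2 difference of 0.01, a mean of -0.10 and a test direction of down, and B cell genes had a median of 0.10, a mean of 0.06 and a test direction of down.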

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

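The fits that left out genes and the block in the 6 tumor libraries were chosen after the result was seen. With an estimated correlation the 16 lists called for resident against marrow-derived macrophages became 1, the 16 for total colony against resident cells 1 and the 4 for Kit-negative against total colony cells 0. Between tumor macrophages, 7157 genes became 6629 to 9027 in the other fits set in advance, 5866 to 6225 with 1 library left out and 4254 without the 6103 genes highest in colony cells. The count of 4254 comes from fewer tested genes, as the 6103 were taken from the 14274, so it does not measure a loss of calls. Between total colony and resident cells, 10165 genes became 9322 to 10536, and 9445 to 10188 with 1 library left out. Between colony groups, 309 genes became 224 to 311 in 5 fits, 18 with only the 6 colony libraries, 836 with DESeq2, 188 with limma, 165 without genes over 10 times higher in tumor macrophages, 187 without X-linked genes and 96 to 386 with 1 library left out. This comparison had 1 list called with library size alone, 2 with a filter of 1 CPM, 1 without the genes higher in tumor macrophages and 0 to 5 with 1 library left out. The cause was not tested.

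With the replicate number as a block, the 3 comparisons gave 7145, 10149 and 224 genes and 16, 16 and 4 lists, and the block in the 6 tumor libraries gave 9163 genes. The block in 12 libraries changed no call of a named gene or list between tumor macrophages. In the 6 tumor libraries, Csf2ra and the primary granule and cholesterol lists changed their call with and without the block, and Itgam with it alone. Same-numbered libraries correlated at -0.10, -0.02 and -0.12 between total colony and resident cells and at -0.21, 0.35 and 0.42 between colony groups, where not every sample correlated best with its own number.

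Of the named genes, 50 of 53 kept their direction and call between tumor macrophages under each alternative that gave them a value, 58 of 61 between total colony and resident cells and 6 of 25 between colony groups. Directions reversed for 3 uncalled genes. Kit between tumor macrophages had a log2 difference of -0.16, or 0.21 without marrow-derived replicate 1, with -0.58 to 0.21 over the libraries left out. Itgam between colony groups had -1.62, or 0.075 without total replicate 2, with -2.08 to 0.075. Col3a1 between total colony and resident cells had 0.08, or -0.09 without resident replicate 3 and -0.46 without total replicate 3, with -0.46 to 0.33. The cause was not tested. At this depth, 3 counts in a library corresponded to 0.0939 to 0.148 CPM, so genes such as Kit in colony cells could not be followed below that level.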

Other observations

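The genes in this paragraph were chosen after their values were seen. Hmga2, a chromatin protein of fetal and transformed cells, stood at 705 ± 61.9 CPM (SD, n = 3) in total colony cells and 49.0 ± 1.44 CPM in resident macrophages. Col4a1, a basement membrane collagen, stood at 1295 ± 210 against 49.2 ± 4.04 CPM. Met, the hepatocyte growth factor receptor, had a log2 difference of 3.55, and the mesenchymal transcription factor genes Prrx1, Twist1 and Snai2 had 3.12, 3.39 and 3.93. Myc rose from 169 ± 6.26 to 472 ± 64 CPM, and the intermediate filament gene Vim fell by 1.33 on the log2 scale.

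Each result stood against the other 9 of the 10 splits of its 6 libraries into groups of 3, which are too few for a share under 0.05. Every other split puts both groups of its comparison on each side, which adds their difference to the spread and lowers the gene count. Between widely different groups, a gap in genes is thus built in. For resident against marrow-derived macrophages, the real split gave 7157 genes and 16 lists and the highest other split 0 genes and 15 lists. Only 1 split reached each count, but 15 lists against 16 hardly set the real split apart. No label pairs these libraries, but their numbers were taken to do so from correlations in the same data. The 3 other splits that part every such pair gave at most 0 genes and 14 lists. Splits that part fewer pairs gave at most 0 genes and 15 lists. For total colony cells against resident macrophages, the real split gave 10165 genes and 16 lists and the highest other split 1 gene and 17 lists, with 1 and 3 splits as large. For Kit-negative against total colony cells, the real split gave 309 genes and 4 lists and the highest other split 2452 genes and 6 lists, with 2 and 3 splits as large. The split with 2452 genes set total replicates 1 and 3 and Kit-negative replicate 3 against the rest, which points to a structure of these samples other than the Kit sort.

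Of the tests in the next 3 paragraphs, those of X-linked genes against expression level and gene length were set before their result was seen, and the others after. Colony libraries held few leukocyte transcripts. The median of 28 such genes reached at most 0.427% of the resident level in any colony library, although Runx1 and Arhgdib kept more. These values argue against blood progenitors that kept general leukocyte genes. They restate the pattern for genes chosen after the data were seen, so they are no separate test. The tables also argue against scaling, which moves all genes alike, since the median log2 difference of these genes lay -8.00 from that of genes matched on level. Cells of the tumor that are not leukocytes stay open: 3 of the 15 fixed epithelial and stromal genes, Krt8, Krt18 and Col3a1, exceeded 20 CPM in each colony library, just at the bound set for this explanation, and 2 of the 15 did so in each resident library too. Krt8 was 12.9-fold higher in total colony than in resident cells, while 8 of 13 tested members, which come from several cell types, were lower, and the gate for resident cells asks for CD45. A loss of macrophage genes in culture was not tested.

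Genes abundant in colony cells were higher in marrow-derived than in resident macrophages. Of 50 such genes, 98% were, against 48.2% of genes matched on level, which carry-over of cells like the colony cells could give. The median of these genes stood at 10.8% of the colony level in marrow-derived and at 3.45% in resident cells. Scaling is argued against, since their median log2 difference of -1.66 lay -1.71 from that of the matched genes. Expression by the marrow-derived macrophages themselves stays open, since the log2 share of the colony level there had an interquartile range of 0.81. These genes were chosen as at least 10 times higher in colony cells than in the mean of both tumor groups. This choice limits that share, so the spread does not decide.

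X-linked genes were higher in Kit-negative than in total colony libraries, with a median log2 difference of 0.35 over 277 genes and autosomal chromosome medians of -0.11 to 0.13. Trends with expression level or gene length are argued against, since matched autosomal genes had medians of 0.007 and 0.002. All of the 14 X chromosome bins of 10 Mb that held 5 or more of the 277 genes, 100%, had a median above 0. A difference in X chromosome dosage between the cells of the 2 groups could give this. Bins with fewer genes were not used, so parts of the chromosome are not covered. Of the bins used, the first 2, with 18 and 13 genes, had only 0.019 and 0.145, against 0.255 to 0.468 in the others. Libraries did not overlap, at -0.15, -0.20 and -0.17 in total and 0.17, 0.16 and 0.19 in Kit-negative cells, and 3 against 3 libraries give an exact p of at least 0.1. Whether a change of dosage covers the whole chromosome, and whether the Kit sort, separate cultures or animals, or chromosome loss or gain in culture set the groups apart was not tested.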
